A study of Mus musculus with 12 samples.

How the data were processed

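Messenger RNA was sequenced from 12 libraries of 2 cultured mouse cell lines. Per the labels' protocols, ID8 cells were detached with trypsin, and pellets of both lines were washed and frozen before a standard Illumina messenger RNA preparation. Each line was measured untreated and after 6 h with 5 nM rebastinib, in 3 libraries per group, which makes 4 groups. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The series design also names chemotherapy arms, and no sample used here carries such a label, so those arms are not analysed here.

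The deposited values were raw counts per gene, as whole numbers for 55421 Ensembl gene identifiers in 1 table. The submitters' processing notes name FastQC, STAR 2.6.1c, featureCounts, DESeq2 and the mouse genome build GRCm38, with no order or role. The annotation used for counting, the strand setting and the treatment of reads that match several places are not given in the sources used here. Values of genes that overlap another gene, have an antisense partner or share sequence with pseudogenes are therefore uncertain, and shared exons are stated for the named genes with the smallest p where the other gene could matter. Symbols, positions, transcript lengths and GC content came from the GENCODE vM21 annotation of the same build, and 267 identifiers with 0.0207% of all counts found no symbol there. A further 107 identifiers shared a symbol with a more abundant one. Library totals ran from 19025504 to 27070556 counts. Count-based intervals and floors (3 counts over a group) cover counting error only.

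Each comparison was tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the default expression filter, and the quasi-likelihood test with robust dispersion, with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Rebastinib was compared with control within each line from that line's 6 libraries. The difference of the response between lines was an interaction contrast over all 12 libraries. Control cells of the lines were compared with a further condition of at least a 2-fold difference. CPM values given beside a fold change were scaled with the same TMM factors. Floors of genes with no count, ratios of counts, and numbers of cell type markers above or below a CPM level used library totals. Gene lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, for lists with at least 5 tested members, adjusted over the lists of a comparison. A total of 38 lists of pathways, quality markers and cell type markers, the tests, the rule for named genes and most alternatives were fixed before the data were examined.

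The genes named follow a rule. For each rebastinib comparison they were the 12 higher and 12 lower genes with the smallest p, leaving out unnamed gene models and pseudogenes. They also include the detected members of Tek, Tie1, Abl1, Kdr, Flt3, Lyn, Csf1r, Angpt1 and Angpt2, and up to 4 members with the smallest p of each list that passed the camera test. For the difference between lines they were the 10 genes with the smallest p. For control cells they were the 10 genes per direction with the largest fold change at 50 or more CPM, with up to 4 macrophage and ovarian markers. A gene outside this rule is named only with a statement that it was chosen after its values were seen.

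The scripts were tested on simulated counts drawn from the means of the control libraries, with a small set of genes changed by a known fold. In ID8 these were 63, 66 and 63 of the tested genes for the smallest to the largest fold. Most simulated genes stayed unchanged, so recovery and false calls were not tested for data in which most genes are called. For genes changed 1.5-fold, 2-fold and 4-fold, edgeR recovered 73.0%, 87.9% and 98.4% in a simulation of the ID8 comparison over 14388 genes. The same shares were 72.7%, 84.1% and 100% for PMJ2R over 13484 genes. They were 48.4%, 57.6% and 78.1% for the difference of response over 16005 genes, and 76.6%, 91.9% and 100% for control cells over 14629 genes. Of the calls, 4.60%, 4.57%, 7.03% and 7.82% were false in the same order, so the difference of response and the control cell simulations lay above the 5% aimed at. In a simulation with a length trend put into the treated libraries, 96.8% of calls were false without and 10.4% with the correction for transcript length and GC content.

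Replicate pairs within each group were compared by a chi-square test of their counts. The statistic per degree of freedom ran from 1.72 to 23.5, so no pair agreed within sampling noise and all libraries were kept. Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library totals without further scaling, no expression filter, a mean of at least 5 CPM, the replicate number as a block, each library left out, a single fit of all libraries, camera with an estimated correlation, and fry. Ranges of adjusted p given for a list cover the alternatives tested by camera at the preset correlation, and so leave out the estimated correlation and fry. A correction for transcript length and GC content, a fit without 3 genes that overlap ribosomal RNA, and a 2-fold minimum were added after seeing the data.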

Results

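The data were gene counts from 12 messenger RNA libraries of 2 mouse cell lines. ID8 is a cancer line derived from ovarian surface epithelium of the C57BL/6 mouse, and PMJ2R is a peritoneal macrophage line. Rebastinib is a small-molecule kinase inhibitor directed at TIE2, the angiopoietin receptor encoded by Tek. The comparisons ask how 6 h of 5 nM rebastinib changed the transcripts of the tumour cell and of the macrophage. ID8 control libraries held 22102800 to 23486355 counts and ID8 rebastinib libraries 19057954 to 24971090. PMJ2R control libraries held 23200008 to 27070556 and PMJ2R rebastinib libraries 19025504 to 20242502.

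Rebastinib libraries of both lines gave a larger share of their counts to a few kinds of abundant transcript. In PMJ2R, 3 genes that overlap ribosomal RNA on chromosome 17 (Gm26917, Gm42418 and CT010467.1, between 39843013 and 39848827) took 5.82% ± 0.184 of counts with rebastinib and 0.128% ± 0.0400 in control (SD, n = 3). In ID8 they took 1.23% ± 0.319 and 0.211% ± 0.129. Mitochondrially encoded genes took 4.94% ± 0.195 with rebastinib and 3.02% ± 0.114 in control in ID8, and 5.64% ± 0.204 and 3.76% ± 0.430 in PMJ2R. Cytosolic ribosomal protein genes took 6.52% ± 0.659 and 3.36% ± 0.263 in ID8, and 5.44% ± 0.111 and 3.69% ± 0.251 in PMJ2R. Genes with at least 10 counts numbered 13788 with rebastinib and 14882 in control in ID8, and 12949 and 14259 in PMJ2R (group means). For each of these measures the rebastinib and control libraries did not overlap, and an exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. The cutoff of 10 counts was not adjusted for library totals. Those totals were lower with rebastinib than in control in PMJ2R (19025504 to 20242502 against 23200008 to 27070556) and overlapped in ID8. Lower totals can by themselves reduce the number of genes that pass the cutoff, and their part in PMJ2R was not tested. The labels give no batch or RNA integrity value. A difference in handling between rebastinib and control libraries therefore cannot be told apart from treatment in any comparison below that uses rebastinib libraries.

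**Figure D1:**
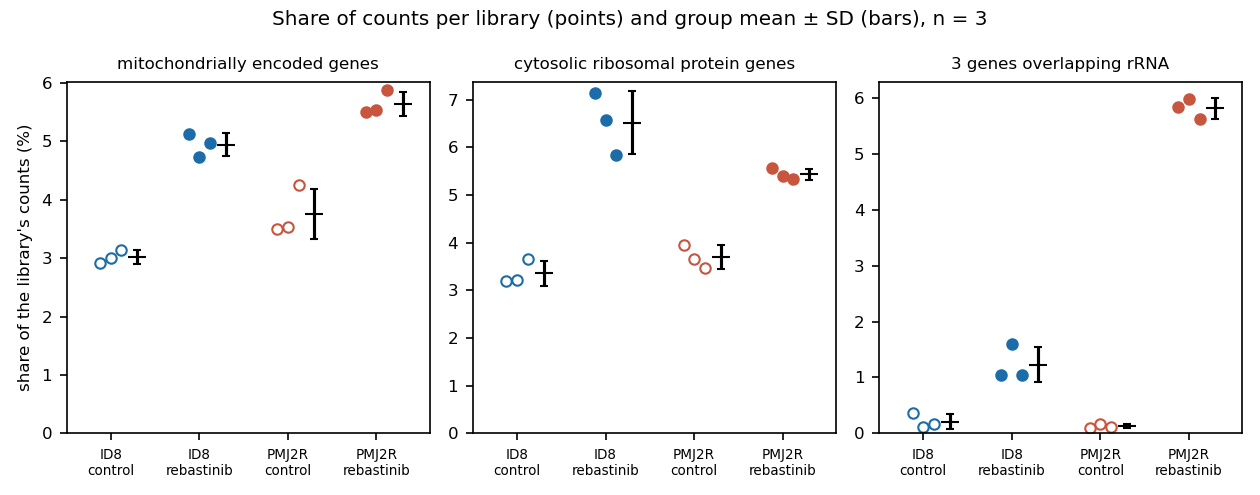
Share of each library's counts (%, vertical axis) in mitochondrially encoded genes, cytosolic ribosomal protein genes and 3 genes that overlap ribosomal RNA, for the 4 groups (horizontal axis). Points are libraries, open for control and filled for rebastinib, and bars are the mean ± SD of 3 libraries; the 3 genes overlapping ribosomal RNA took 5.82% of counts in PMJ2R with rebastinib and 0.128% in control.

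The control cells of the lines carried most of the listed markers of their tissues. Of 26 macrophage markers, 6 stood under 1 CPM in PMJ2R, and of 26 ovarian and mesothelial markers, 4 did in ID8. Krt19, which encodes an epithelial keratin, stood at 1660 ± 75.6 CPM in ID8 control cells and at 0 in PMJ2R, at least 40400-fold higher in ID8 against a floor of 3 counts over the group. Other transcripts with no count in PMJ2R control cells were the proteoglycan gene Bgn (at least 32800-fold higher in ID8), the collagen chaperone gene Serpinh1 (at least 23200-fold), the keratin gene Krt18 (at least 19400-fold), Tm4sf1 (at least 18100-fold), Chchd10 (at least 12900-fold, with exons shared with Mmp11 and Gm867 on the opposite strand), Cdr2l (at least 12500-fold), Cyp1b1 (at least 10600-fold), Cpe (at least 7920-fold) and Gpm6a (at least 7850-fold). In PMJ2R the lysosomal membrane gene Laptm5 stood at 772 ± 48.2 CPM and was at least 17900-fold higher than in ID8, where it had no count. Wdfy4 (at least 10000-fold higher), Parvg (at least 5500-fold), Adgre1, which encodes the macrophage surface protein F4/80 (at least 5450-fold), Ctss (at least 5310-fold), Hpgd (at least 5060-fold), the myeloid transcription factor gene Spi1 (at least 4530-fold), Ighm (at least 4460-fold), Vav1 (at least 3620-fold) and Cyba (at least 3520-fold) likewise had no count in ID8.

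Of 15924 genes tested between control cells, 2890 were higher in PMJ2R and 4076 lower at a 2-fold minimum (edgeR quasi-likelihood test). Of 21 macrophage markers tested, 20 were higher in PMJ2R and 1 lower, and the list was called higher (camera adjusted p = 5.20e-24). All 22 tested markers of ovarian surface epithelium and mesothelium were higher in ID8 (camera adjusted p = 1.23e-24). Neither list held with an estimated correlation (adjusted p = 0.0674 for each), and both counts were the same under the other 3 scalings and adjusted over the list alone. Ptprc, which encodes the leukocyte antigen CD45, had 1 count in ID8 and a PMJ2R to ID8 ratio of 31900 (95% counting interval 5730 to 1260000). The macrophage marker lower in PMJ2R was Gata6, a transcription factor of resident peritoneal macrophages that is also on the ovarian list, at 158 ± 6.45 CPM in ID8 and a ratio of 5770 in favour of ID8 (1600 to 47600). Krt8 had a ratio of 62900 in favour of ID8 (11300 to 2480000), and the mesothelial antigen gene Msln 9640 (2670 to 79600). Wt1, the Wilms tumour transcription factor gene, stood at 593 ± 23.4 CPM in ID8 control cells and had 4 counts over the PMJ2R control libraries. Of the tested lists, 14 were called between control cells and none with an estimated correlation. Antigen presentation genes were higher in PMJ2R (17 of 20 higher and 2 lower, camera adjusted p = 0.000282, or 0.166 with an estimated correlation), as were MYC targets and ribosome biogenesis genes (29 of 30 higher and 1 lower, adjusted p = 4.03e-06, or 0.258). Matrix genes were lower (26 of 30 lower and 3 higher, or 26 and 4 adjusted over the list alone, adjusted p = 1.23e-24, or 0.154), as were immediate-early genes (15 of 20 lower and 3 higher, adjusted p = 0.000887, or 0.343).

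The transcript of the receptor that rebastinib is directed at had almost no counts in these cells. Tek had 0 counts in both ID8 groups, which allows up to 0.0443 CPM in control and 0.0460 with rebastinib, and 8 and 2 counts in PMJ2R control and rebastinib. Tie1 had 0 counts in ID8 and 1 and 6 in PMJ2R, and Kdr had 0 in ID8 and 1 and 2 in PMJ2R, so neither could be compared at this depth. Angpt1 had 8 and 1 counts in ID8 and 2 and 0 in PMJ2R. Kinase genes that were measured included Csf1r, at 315 ± 12 CPM in PMJ2R and 8.03 ± 0.367 in ID8 control cells (log2 fold change 5.30, SE 0.0756, adjusted p = 4.32e-22), and Lyn, at 75.4 ± 1.90 and 22.6 ± 1.05 (1.74, SE 0.0666, adjusted p = 2.62e-15). Flt3 had no count in ID8 and was at least 162-fold higher in PMJ2R. Abl1 did not differ past the test's threshold (0.02, SE 0.0688, adjusted p = 0.815), and the ligand gene Angpt2 was higher in PMJ2R at a low level (1.77, SE 0.398, adjusted p = 0.000426).

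In ID8 with rebastinib, the list of NRF2 antioxidant genes was called higher (camera adjusted p = 1.35e-05), and the lists of interferon-stimulated (0.00428), cholesterol synthesis (0.00617) and mitosis genes (0.00104) were called lower. None of the lists tested in ID8 was called with an estimated correlation (lowest adjusted p = 0.549). Nqo1, a quinone reductase (chromosome 8, 107388225 to 107403206, GRCm38), rose from 42.6 ± 2.90 to 360 ± 31.1 CPM (log2 fold change 3.08, SE 0.0851, edgeR adjusted p = 3.03e-12, n = 3). Ahrr, the repressor of the aryl hydrocarbon receptor (chromosome 13, 74211118 to 74292331), rose from 3.71 ± 0.270 to 57.7 ± 2.28 CPM (3.96). Id2 and Id3, inhibitors of helix-loop-helix transcription factors, rose by 3.54 and 3.62. Chac1, which encodes a glutathione-degrading enzyme (chromosome 2, 119351229 to 119354381), fell by 4.64, and Xbp1, a transcription factor gene of the unfolded protein response (chromosome 11, 5520659 to 5525893), fell by 3.01.

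The higher genes with the smallest p in ID8 also included Cep295nl (6.20, SE 0.123) and the urea transporter gene Slc14a1 (6.21, SE 0.133), each with an adjusted p of 4.1e-13. The splicing and transcription cofactor gene Rbm14 (2.87), the transcription factor gene Atoh8 (3.77), the pantetheinase gene Vnn1 (2.78), the glypican gene Gpc1 (2.53), the ascorbate transporter gene Slc23a2 (2.20) and Vps37b (2.14) followed. Rbm14 shares exons with Gm21992 on its own strand, Gpc1 with Ankmy1 and Vps37b with Hip1r on the opposite strand, so reads of these pairs cannot be told apart. The lower genes were led by Mdc1, a mediator of the DNA damage checkpoint, which went from 187 ± 8.31 to 6.29 ± 0.912 CPM (-4.88, SE 0.102), and Zc3h4 (-4.56, SE 0.0974, exons shared with Gm45510 on the opposite strand). Sorbs3 (-3.24), Sema4g (-3.57), Prr15l (-4.62), C1qtnf1 (-3.18), Tnks1bp1 (-2.78), Ppp1r9b (-2.92), Helz2 (-4.86) and Igsf9 (-4.66) also fell. Of these, Sorbs3, Prr15l and C1qtnf1 share exons with a gene on the opposite strand. Every named gene separated all 3 rebastinib from all 3 control libraries. The choice by smallest p on these same libraries favours that, so it adds no support.

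Among the kinase genes in ID8, Csf1r rose from 6.71 ± 0.270 to 12.8 ± 1.97 CPM (0.93, SE 0.128, adjusted p = 1.08e-05) and Lyn from 18.9 ± 1.01 to 31.4 ± 2.31 (0.73, SE 0.0910, adjusted p = 3.62e-06). Abl1 fell by 0.39 (SE 0.0798, adjusted p = 0.000442), but stood at 0.04 (adjusted p = 0.589, range over its alternatives 2.23e-06 to 0.589) once trends of transcript length and GC content were removed. The list of kinase targets and ligands had 4 members higher and 4 lower of 9 tested, with a median of -0.12, a mean of 0.15 and no camera call (adjusted p = 0.886).

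Interferon-stimulated genes fell in ID8: 23 of 28 tested members fell and 2 rose (median log2 fold change -1.97, camera adjusted p = 0.00428, adjusted p = 0.549 with an estimated correlation). Stat2, a transcription factor gene of interferon signalling, fell by 2.88, Parp14 by 4.68, Oasl2 by 2.90 and Herc6 by 2.83. The list was not called among genes with a mean of at least 5 CPM (median -0.89, adjusted p = 0.121, range over alternatives 0.000144 to 0.121 at the preset correlation). Of 24 genes of cholesterol synthesis and LDL uptake, 17 fell and 1 rose (median -0.58, adjusted p = 0.00617, or 0.549 with an estimated correlation). Insig1, the sterol sensor partner, went from 253 ± 2.22 to 42.5 ± 5.55 CPM (-2.57), and the synthesis enzymes Nsdhl (-1.89), Pmvk (-1.27) and Msmo1 (-0.99) fell. Of 36 genes of G2/M and mitosis, 28 fell and 6 rose (median -0.54, adjusted p = 0.00104, or 0.549 with an estimated correlation). The mitotic kinase gene Nek2 fell by 2.95, the proliferation marker Mki67 by 2.06, from 728 ± 43.3 to 175 ± 16.6 CPM, and the topoisomerase gene Top2a (-1.75) and the kinesin gene Kif2c (-1.42) fell too.

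Ribosomal protein and respiratory genes were called higher in ID8. All 46 cytosolic ribosomal protein genes rose (median 1.38, camera adjusted p = 2.46e-15, or 0.556 with an estimated correlation), among them Rpl4 (1.42), Rpl22 (1.86) and Rpl35 (1.61). All 41 tested nuclear-encoded genes of oxidative phosphorylation rose (median 1.26, adjusted p = 2.04e-14, or 0.549 with an estimated correlation), such as Sdhd (1.38), Ndufa4 (1.57), Uqcrc1 (1.24) and Cox5a (1.37). Of 13 mitochondrially encoded genes, 12 rose (median 1.48, adjusted p = 0.000265, or 0.549 with an estimated correlation), with mt-Nd1 at 1.57, mt-Nd4 at 1.63, mt-Nd2 at 1.16 and mt-Nd6 at 1.48. Once trends of transcript length and GC content were removed, the ribosomal protein median was 0.54 with 44 of 46 higher (adjusted p = 4.09e-08) and the oxidative phosphorylation median 0.46 with 35 of 41 higher (1.66e-06), and the mitochondrial list was not called (median 0.36, adjusted p = 0.112, range over alternatives 3.28e-07 to 0.112 at the preset correlation). Of 30 MYC targets and ribosome biogenesis genes, 22 rose and 6 fell (median 0.82, adjusted p = 0.000232, or 0.549 with an estimated correlation), with Gnl3 (1.35), Rrs1 (1.34), Fbl (1.77) and Nop56 (1.37) higher, of which Gnl3 and Nop56 hold small nucleolar RNA genes in their exons. The same libraries had the larger shares of counts in ribosomal protein, mitochondrial and ribosomal RNA overlapping genes given above.

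Antioxidant, heat shock and lysosomal genes were called higher in ID8 too. Of 24 NRF2 antioxidant genes, 19 rose and 1 fell (median 0.78, camera adjusted p = 1.35e-05, or 0.549 with an estimated correlation). Beside Nqo1 these included the haem oxygenase gene Hmox1 (1.85), the glutathione synthesis gene Gclm (1.32) and the ferritin light chain gene Ftl1, from 1350 ± 84.4 to 5860 ± 1070 CPM (2.12). Of 17 heat shock genes, 15 rose and 1 fell, or 16 and 1 adjusted over the list alone (median 0.79, adjusted p = 0.000265, or 0.549 with an estimated correlation), with Bag3 (1.57), Hspb1 (1.92), Cacybp (1.22) and Hspe1 (1.69, exons shared with Hspd1 on the opposite strand). Of 27 genes of phagocytic receptors and lysosomes, 20 rose and 2 fell, or 21 and 2 adjusted over the list alone (median 0.67, adjusted p = 1.35e-05, or 0.549 with an estimated correlation). The cathepsin genes Ctsl (1.90) and Ctsb (1.56), the proton pump gene Atp6ap1 (1.65) and the lysosomal membrane gene Lamp1 (1.51) were among them. Of 25 p53 targets, 17 rose and 4 fell (median 0.62, adjusted p = 0.0481, or 0.602 with an estimated correlation), including Zmat3 (1.80), Plk2 (1.34), Perp (1.29) and Gtse1 (1.07). The p53 call was lost with library totals only (adjusted p = 0.0812), among genes with a mean of at least 5 CPM (0.121), and without control replicate 1 (0.0533), control replicate 3 (0.0594) or rebastinib replicate 3 (0.0557), over a range of 0.00929 to 0.121 at the preset correlation.

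Other lists were not called in ID8. Immediate-early genes had 5 members higher and 14 lower of 20 (median -0.59, camera adjusted p = 0.105), and were called without rebastinib replicate 2 (adjusted p = 0.0491) and with no expression filter (0.00986; range 0.00986 to 0.157 at the preset correlation). Hypoxia and glycolysis genes had 10 higher and 19 lower of 33 (median -0.44, adjusted p = 0.105, called with library totals only at 0.0182 and with no filter at 0.00929, range 0.00929 to 0.134 at the preset correlation), ERK feedback genes 5 and 8 of 17 (median -0.06, adjusted p = 0.972), and G1/S and DNA replication genes 8 and 17 of 34 (median -0.17, adjusted p = 0.0605, called without rebastinib replicate 1 at 0.0345, with library totals only at 0.00586, with no filter at 0.00251, at 5 CPM at 0.0435 and with length and GC trends removed at 0.0218, range 0.00251 to 0.0844 at the preset correlation). Targets of ATF4 had 17 higher and 9 lower of 31, with a median of 0.32, or -0.11 with library totals only, against a mean of -0.17 (adjusted p = 0.972). The median, mean or test also differed in sign for the kinase targets, classical macrophage markers, matrix genes and SRF targets.

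In all, 5687 genes were higher and 6230 lower of 14829 tested in ID8 (11917 called, 80.4%; edgeR quasi-likelihood test). With at least a 2-fold difference, 2309 were higher and 3622 lower. Of the 11917 genes, 11695 had no overlap between the 3 rebastinib and 3 control libraries. Chance alone gives that for 10% of unselected genes, but these were selected by the test on the same libraries, so the count adds no support. Each fold change is relative to the scaling: with library totals only, all genes shifted by -0.43 and 3540 were higher and 8475 lower. The medians of the 11 called lists kept their sign under each scaling, and adjusted over the list alone the counts of the called lists were the same except where given.

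In PMJ2R with rebastinib, the lists of ATF4 targets (camera adjusted p = 3.37e-12), ERK feedback genes (0.00134) and NRF2 antioxidant genes (0.000533) were called higher, and those of DNA replication (3.55e-11), mitosis (4.77e-13) and interferon-stimulated genes (0.0401) were called lower. None of the lists tested in PMJ2R was called with an estimated correlation (lowest adjusted p = 0.0720). Aqp9, an aquaglyceroporin gene (chromosome 9, 71110659 to 71168682), rose from 10.4 ± 0.695 to 133 ± 1.50 CPM (log2 fold change 3.67, SE 0.0624, edgeR adjusted p = 1.28e-17, n = 3). Ero1l, which encodes an oxidase of the endoplasmic reticulum (chromosome 14, 45283087 to 45318771), rose by 2.71, and Ddit4, an inhibitor of mTORC1 signalling (chromosome 10, 59949669 to 59951834), by 2.78. The immediate-early genes Ier2 and Junb rose by 3.21 and 2.32. Rassf4 (chromosome 6, 116633008 to 116673952) fell by 5.16, from 108 ± 2.92 to 3 ± 0.48 CPM, and Ptpn6, which encodes the phosphatase SHP-1 (chromosome 6, 124720707 to 124738714), fell by 3.12.

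Further genes with the smallest p among the higher ones were Pid1 (3.36), Pdzd8 (2.37), the glucosylceramide synthase gene Ugcg (2.55), the degradation channel gene Derl1 (2.25), the stress sensor gene Sesn2 (2.6), Susd6 (2.50) and the thiamine transporter gene Slc19a2 (2.40). The lower genes included the secretory carrier gene Scamp5 (-3.02), the phosphoinositide 3-kinase gene Pik3cd (-4.03), the DNA polymerase subunit gene Pola2 (-2.86), Ptpn7 (-2.96), the prostaglandin dehydrogenase gene Hpgd (-3.69), Cbx6 (-3.72), Nek2 (-3.26), the histone methyltransferase gene Setdb1 (-3.30), Hip1 (-3.18) and Zc3h4 (-3.76). Junb shares exons with Prdx2, Ptpn6 with Gm20531, Setdb1 with Cers2 and Zc3h4 with Gm45510 on the opposite strand, and Cbx6 with Npcd on its own strand. Every named gene separated all 3 rebastinib from all 3 control libraries, which the choice by smallest p favours, so it adds no support.

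Among the kinase targets and ligands in PMJ2R, Csf1r, the receptor of macrophage colony-stimulating factor (chromosome 18, 61100598 to 61132149), fell from 268 ± 11.4 to 146 ± 2.56 CPM (-0.87, SE 0.0466, adjusted p = 5.04e-12). Abl1 fell by 1.27 (SE 0.0663, adjusted p = 3.75e-12) and Flt3 by 1.03 (SE 0.143, adjusted p = 2.62e-06). Lyn rose by 1.09 (SE 0.0502, adjusted p = 6.96e-13) and Angpt2 from 0.895 ± 0.275 to 3.87 ± 0.767 CPM (2.12, SE 0.234, adjusted p = 1.42e-07). The list had 3 members higher and 6 lower of 9 tested (median -0.87, camera adjusted p = 0.600).

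Targets of ATF4 and the amino acid response rose in PMJ2R: 25 of 29 tested members rose and 3 fell (median 1.04, camera adjusted p = 3.37e-12, or 0.142 with an estimated correlation). They included the cystine transporter gene Slc7a11 (2.96), the cysteine synthesis gene Cth, from 1.59 ± 0.222 to 41.9 ± 3.27 CPM (4.71), the asparagine synthetase gene Asns (1.79) and Sesn2. Feedback genes of the ERK pathway rose, with 13 of 15 higher and 1 lower (median 0.84, adjusted p = 0.00134, or 0.415 with an estimated correlation). The ERK inhibitor gene Spry4 rose by 4.54, the phosphatase gene Dusp5 by 2.83, the ephrin receptor gene Epha2 by 2.48 and the transcription factor gene Etv1 by 2.21. Of 18 immediate-early genes, 11 rose and 6 fell (median 0.69, adjusted p = 0.00744, or 0.415 with an estimated correlation), with Klf6 at 2.0 and Ier3 at 3.16. Of 23 NRF2 antioxidant genes, 15 rose and 4 fell (median 0.72, adjusted p = 0.000533, or 0.142 with an estimated correlation), with Hmox1 at 1.88, Ftl1 at 1.80 and the autophagy receptor gene Sqstm1 at 1.24. Of 32 genes of phagocytic receptors and lysosomes, 23 rose and 8 fell (median 0.64, adjusted p = 0.00204, or 0.289 with an estimated correlation), with Ctsb (1.63), Ctsd (1.50), Atp6ap1 (1.41) and the inhibitory Fc receptor gene Fcgr2b (1.56) higher.

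Genes of DNA replication and of mitosis were called lower in PMJ2R. Of 34 genes of G1/S and DNA replication, 30 fell and 2 rose (median -1.17, camera adjusted p = 3.55e-11, or 0.142 with an estimated correlation). The methylation maintenance gene Uhrf1 fell by 2.46, the replication factor gene Mcm10 by 3.66, the checkpoint adaptor gene Clspn by 2.94 and the ribonucleotide reductase gene Rrm2 by 1.75. Of 36 genes of G2/M and mitosis, 32 fell and 2 rose (median -1.17, adjusted p = 4.77e-13, or 0.0720 with an estimated correlation). Mki67 fell by 2.02, from 869 ± 45.4 to 214 ± 7.69 CPM, and Kif2c (-2.73) and Top2a (-1.84) fell too. Interferon-stimulated genes fell, with 12 of 19 lower and 3 higher (median -1.67, adjusted p = 0.0401, or 0.289 with an estimated correlation), and Stat2 (-3.88), Ifit2 (-5.16), Irf7 (-2.97) and Parp14 (-5.47) among the lower ones. That call was lost with library totals only (adjusted p = 0.177), among genes with a mean of at least 5 CPM (0.131) and without control replicate 3 (0.0775), over a range of 0.00655 to 0.177 at the preset correlation.

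Ribosomal protein and respiratory genes were called higher in PMJ2R as well. All 46 cytosolic ribosomal protein genes rose (median 1.09, camera adjusted p = 1.01e-15, or 0.415 with an estimated correlation), with Rplp2 (1.44), Rpl10a (1.26), Rps15 (1.23) and Rpl4 (1.24) named by the rule. All 41 oxidative phosphorylation genes rose (median 0.84, adjusted p = 4.86e-10, or 0.415 with an estimated correlation), such as Uqcrq (1.39), Cox4i1 (1.28), Atp5b (1.14) and Ndufa8 (1.05). All 12 tested mitochondrially encoded genes rose (median 1.22, adjusted p = 0.00493, or 0.476 with an estimated correlation), with mt-Co1 at 1.31, mt-Nd4 at 1.12, mt-Nd2 at 1.07 and mt-Nd1 at 1.07. With trends of transcript length and GC content removed, the ribosomal protein median was 0.65 with 44 of 46 higher (adjusted p = 2.78e-08) and the oxidative phosphorylation median 0.33 with 31 of 41 higher (0.000486). In the same fit the mitochondrial list was not called (median 0.34, adjusted p = 0.471, range over alternatives 1.73e-06 to 0.471 at the preset correlation), nor were mt-Nd4 (0.46, adjusted p = 0.0525, the highest over its alternatives, the lowest being 7.52e-86), mt-Nd2 (0.23, adjusted p = 0.319, lowest 7.79e-76) and mt-Nd1 (0.19, adjusted p = 0.390, lowest 4.74e-71). The rebastinib libraries of PMJ2R were also those with 5.82% of counts in genes that overlap ribosomal RNA.

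The hypoxia and p53 lists of PMJ2R depended on the scaling. Of 30 hypoxia and glycolysis genes, 18 rose and 11 fell, with a median of 0.40, or -0.15 with library totals only (camera adjusted p = 0.0281, or 0.555 with an estimated correlation). The angiogenic growth factor gene Vegfa rose by 2.50 and the glycolysis genes Pfkp and Pgam1 by 1.08 and 1.03. The call was lost with library totals only (adjusted p = 0.233), with no expression filter (0.290) and among genes with a mean of at least 5 CPM (0.0736), over a range of 0.000752 to 0.290 at the preset correlation. Of 22 p53 targets, 13 rose and 8 fell, with a median of 0.32, or -0.23 with library totals only (adjusted p = 0.0392, or 0.289 with an estimated correlation). The apoptosis gene Bbc3 rose by 1.87, Plk3 by 2.50, Zmat3 by 1.16 and the stress cytokine gene Gdf15 by 4.84, from 0.313 ± 0.120 to 9.23 ± 0.397 CPM. The p53 call was lost with library totals only (adjusted p = 0.103), with no filter (0.152), among genes with a mean of at least 5 CPM (0.140) and without control replicate 3 (0.0764), over a range of 0.0199 to 0.152 at the preset correlation.

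Lists not called in PMJ2R included cholesterol synthesis and LDL uptake, with 16 members higher and 6 lower of 24 and a median of 0.44, or -0.12 with library totals only (camera adjusted p = 0.113; called at 0.0261 with length and GC trends removed, range 0.0261 to 0.593 at the preset correlation). Macrophage markers had 12 higher and 7 lower of 20 and a median of 0.44, or -0.12 with library totals only (adjusted p = 0.308). MYC targets and ribosome biogenesis genes had 17 higher and 10 lower of 30 (adjusted p = 0.230), and heat shock genes 8 and 5 of 15 (adjusted p = 0.343), both with a median above 0 that fell below it with library totals only. The median, mean or test differed in sign for NF-kB targets, matrix genes and antigen presentation genes.

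In all, 5623 genes were higher and 6107 lower of 14010 tested in PMJ2R (11730 called, 83.7%; edgeR quasi-likelihood test). With at least a 2-fold difference, 2187 were higher and 3606 lower. Of the called genes, 11504 had no overlap between the groups' libraries, a count that the test itself selects for, as in ID8. With library totals only, all genes shifted by -0.56 and 3104 were higher and 8677 lower. Under each scaling 11 of the 13 called lists kept the sign of their median, the exceptions being hypoxia and p53 targets, and adjusted over the list alone the counts of the called lists were the same.

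**Figure D2:**
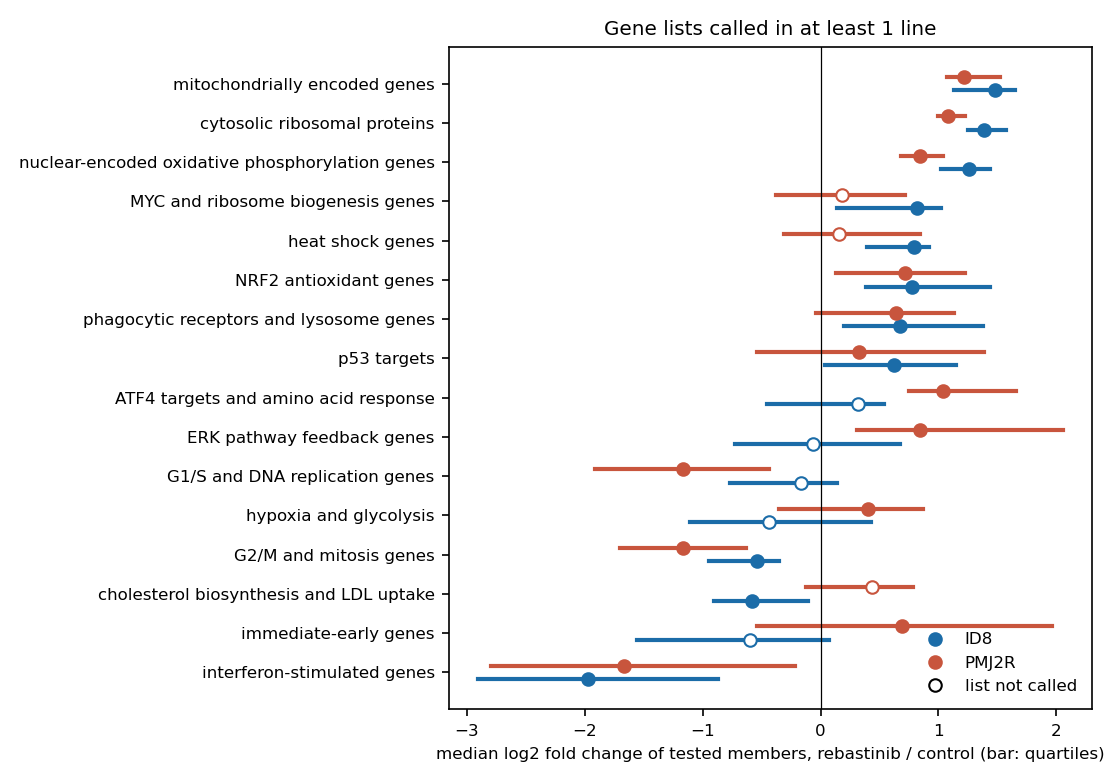
Median log2 fold change of the tested members of each gene list, rebastinib over control (horizontal axis), for lists called in at least 1 line (vertical axis). Points are medians, filled where the list was called, and bars run between the quartiles; cytosolic ribosomal proteins stand at 1.38 in ID8 and 1.09 in PMJ2R, and interferon-stimulated genes at -1.97 and -1.67, with hypoxia and p53 targets of PMJ2R turning to -0.15 and -0.23 with library totals only.

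The responses of the lines were positively related across genes. Over 12398 genes tested in both lines the log2 fold changes had a Pearson correlation of 0.703 and a Spearman correlation of 0.703. Genes are not independent replicates, so no p is given. The Pearson value ran from 0.688 to 0.710 when each library was left out in turn, and was 0.708 with limma-voom. With DESeq2, fitted without the expression filter and so over more genes, it was 0.414. Higher in both lines were 3711 genes, against 2132 for independent lists (odds ratio 10.6), and lower in both were 3741, against 2091 (odds ratio 12.5). Opposite directions were called for 692 genes that were higher in ID8 and lower in PMJ2R and for 537 that were lower in ID8 and higher in PMJ2R. In both lines the log2 fold change of coding genes followed mean expression (Spearman correlation 0.398 in ID8 and 0.413 in PMJ2R) and transcript length (-0.311 and -0.135). Such shared trends can raise the correlation and the overlaps, which were not recomputed with the trends removed.

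**Figure D3:**
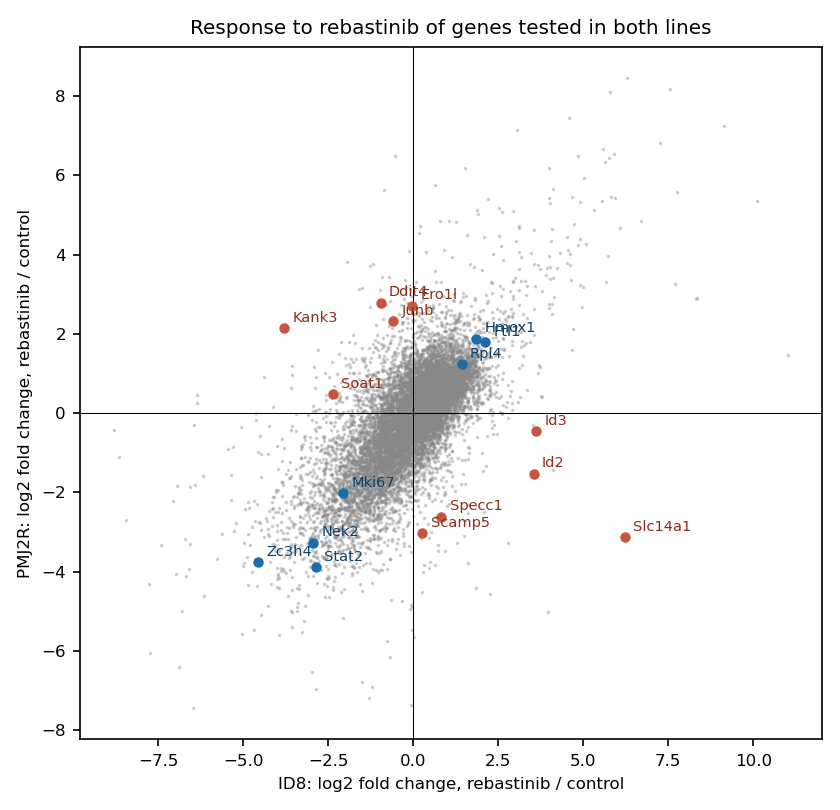
Log2 fold change of each gene tested in both lines, rebastinib over control, in ID8 (horizontal axis) and PMJ2R (vertical axis). Red points are the 10 genes with the smallest p for a different response and blue points are genes that moved the same way, such as Stat2 at -2.88 and -3.88; the correlation across genes was 0.703.

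The response itself differed between the lines for 3 lists that were also called with an estimated correlation: cholesterol synthesis (adjusted p = 0.00615 with an estimated correlation), G1/S and DNA replication (0.00615) and ATF4 targets (0.0399). Id2 rose by 3.54 in ID8 and fell by 1.52 in PMJ2R, a difference of -5.12 (PMJ2R minus ID8, SE 0.119, edgeR adjusted p = 2.52e-19). Id3 rose by 3.62 in ID8 and fell by 0.45 in PMJ2R (difference -4.12). Ddit4 fell by 0.96 in ID8 and rose by 2.78 in PMJ2R (3.69, SE 0.0929, adjusted p = 7.89e-19), and Junb fell by 0.60 and rose by 2.32 (2.86). Slc14a1 rose by 6.21 in ID8 and fell by 3.13 in PMJ2R (-9.40, SE 0.257).

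The remaining genes of the 10 with the smallest p were the following. Specc1 rose by 0.82 in ID8 and fell by 2.61 in PMJ2R (difference -3.49). Scamp5 rose by 0.26 and fell by 3.02 (-3.34). Kank3, which shares exons with Rps28 on the opposite strand, fell by 3.79 and rose by 2.14 (5.88). Soat1, which encodes the enzyme that esterifies cholesterol, fell by 2.37, from 1310 ± 46.4 to 251 ± 22.4 CPM in ID8, and rose by 0.48 in PMJ2R (2.80). Ero1l stood at -0.04 in ID8 (adjusted p = 0.596) and rose by 2.71 in PMJ2R (2.69).

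**Figure D4:**
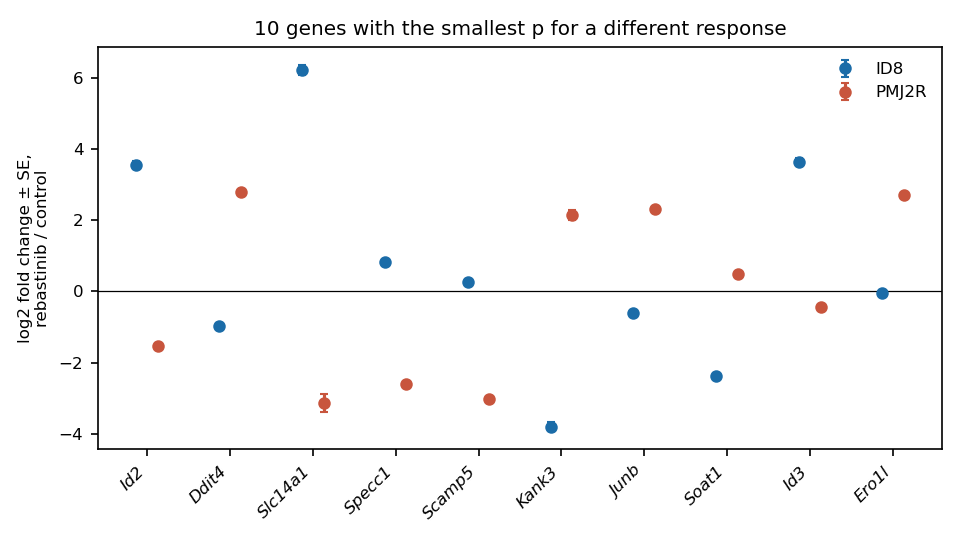
Log2 fold change ± SE, rebastinib over control (vertical axis), in ID8 and PMJ2R for the 10 genes with the smallest p for a different response (horizontal axis). The lines take opposite signs, as in Id2 at 3.54 in ID8 and -1.52 in PMJ2R, with the exception of Ero1l, whose value in ID8 (-0.04) did not pass the test.

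Immediate-early genes responded more positively in PMJ2R, with 14 of 21 tested members higher and 2 lower in the difference (median 1.32, or 1.04 over the 17 members tested in both lines; camera adjusted p = 3.24e-09, or 0.0813 with an estimated correlation). ERK feedback genes did so with 14 of 17 higher and 2 lower (median 1.52, or 1.06 over 15 members; adjusted p = 2.77e-08, or 0.0813 with an estimated correlation). Cholesterol synthesis genes had 19 of 24 higher and 2 lower (median 1.07, adjusted p = 5.28e-13, and 0.00615 with an estimated correlation), and targets of ATF4 25 of 31 higher and 1 lower (median 0.85, or 0.80 over 29 members; adjusted p = 1.44e-19, and 0.0399 with an estimated correlation). Hypoxia and glycolysis genes had 16 of 33 higher and 2 lower (median 0.41, or 0.34 over 30 members tested in both lines; adjusted p = 3.14e-08, or 0.280 with an estimated correlation). The difference was also called higher for alternative macrophage markers, with 7 of 14 higher and 1 lower (median 1.72, or 2.63 over the 6 members tested in both lines, adjusted p = 0.0141, or 0.349 with an estimated correlation). Within PMJ2R that list had 6 members higher and 5 lower of 14 (median 0.01, camera adjusted p = 0.600). Within ID8 it had 1 higher and 4 lower of 6 (median -1.16, adjusted p = 0.211). SRF targets were called higher in the difference with 9 of 21 higher and 5 lower (median 0.55, or 0.41 over 18 members and 0.26 with length and GC trends removed, adjusted p = 0.0114, or 0.488). Angiogenic factors were too, with 10 of 26 higher and 3 lower (median 0.65, or 0.60 over the 12 members tested in both lines, adjusted p = 0.0493, or 0.489).

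G1/S and DNA replication genes responded more negatively in PMJ2R, with 28 of 34 lower and none higher, or 31 adjusted over the list alone (median -0.87, camera adjusted p = 7.36e-13, and 0.00615 with an estimated correlation). Genes of G2/M and mitosis had 29 of 36 lower and 1 higher (median -0.69, adjusted p = 2.66e-09, or 0.0725 with an estimated correlation). Heat shock genes had 12 of 17 lower and 1 higher (median -0.52, adjusted p = 0.00189, or 0.349 with an estimated correlation). MYC targets and ribosome biogenesis genes had 21 of 30 lower and 2 higher, or 21 and 4 adjusted over the list alone (median -0.43, adjusted p = 0.000134, or 0.349 with an estimated correlation). Oxidative phosphorylation genes had 33 of 41 lower and none higher, or 33 and 1 adjusted over the list alone (median -0.48, adjusted p = 0.000709, or 0.751 with an estimated correlation). Cytosolic ribosomal protein genes had 31 of 46 lower, or 35 adjusted over the list alone (median -0.35, adjusted p = 0.0141, or 0.819 with an estimated correlation). With length and GC trends removed, the call was lost for oxidative phosphorylation (median -0.10, adjusted p = 0.593, range over its alternatives 0.000151 to 0.593 at the preset correlation) and for ribosomal proteins (median 0.02, adjusted p = 0.655, range 0.00612 to 0.655 at the preset correlation).

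Of 16566 genes tested for a different response, 3618 were more positive and 5066 more negative in PMJ2R (8684 called, 52.4%; edgeR quasi-likelihood test). With RLE size factors, which shifted all genes by 0.12, the counts were 4260 and 4198, and with DESeq2, which also shifted them by 0.12, 4358 and 4111. Of the called genes, 7772 were tested in both lines, and 4168 of these were called in the same direction in each line. The medians of the 14 called lists kept their sign under each scaling.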

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

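The tests of mitochondrially encoded and oxidative phosphorylation genes below, and the use of a bootstrap interval for ribosomal protein genes, were chosen only after the result was seen; the list of aryl hydrocarbon receptor targets and the choice of the 3 lists weighed for the difference between lines were made after seeing the data.

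A difference between the cell lines, found by the test of the interaction, singled out the following. Of 16566 genes, 3618 responded more positively and 5066 more negatively in PMJ2R than in ID8. The differences of response (PMJ2R minus ID8, log2) were -5.12 for Id2, 3.69 for Ddit4, -9.40 for Slc14a1, -3.49 for Specc1, -3.34 for Scamp5, 5.88 for Kank3, 2.86 for Junb, 2.80 for Soat1, -4.12 for Id3 and 2.69 for Ero1l. List medians were 1.32 for immediate-early genes, 1.52 for ERK feedback genes, 1.72 for alternative macrophage markers, 1.07 for cholesterol synthesis, 0.41 for hypoxia and glycolysis, 0.85 for ATF4 targets, 0.65 for angiogenic factors and 0.55 for SRF targets. They were -0.87 for G1/S genes, -0.69 for G2/M genes, -0.43 for MYC targets, -0.35 for cytosolic ribosomal proteins, -0.48 for oxidative phosphorylation and -0.52 for heat shock genes.

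Whether the groups could have differed by chance was tested with every split of the libraries. Of the 10 splits of 6 libraries into 3 and 3, only the real split (1 of 10) called as many genes, with 11917 in ID8, 11730 in PMJ2R and 6966 between control cells. The highest other split called 0 by edgeR, with 22, 21 and 42 genes at an unadjusted p below 0.05. Every other split mixed the real groups, so the difference between them entered the spread within each side and left few genes to call. The low counts of the other splits therefore exclude nothing here, and 10 splits are also too few for a share under 0.05. For the difference of response, 1 of 100 drawn splits (the real one) reached 8684 genes, and the highest other gave 5836 after 2 ID8 labels were exchanged and the PMJ2R labels were kept, but exchanging labels within a line also breaks up the treatment effect shared by the lines, so a small share of splits excludes nothing here, although it was set beforehand to speak against chance.

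Ribosomal protein and respiratory genes were higher in both lines, and shorter transcripts were higher too (Spearman correlation of log2 fold change with transcript length -0.311 in ID8 and -0.135 in PMJ2R). More abundant genes were higher as well (correlation with mean expression 0.398 in ID8 and 0.413 in PMJ2R), and that trend was not corrected for. With length and GC trends removed, the ribosomal protein median went from 1.38 to 0.54 in ID8 (95% bootstrap interval 0.48 to 0.67) and from 1.09 to 0.65 in PMJ2R (0.51 to 0.73), so a part of the rise remained. All bootstrap intervals in this paragraph resampled the genes of a set and not the libraries. They treat genes as independent, while the estimated correlation between ribosomal protein genes was 0.887 in ID8. The intervals therefore leave out the spread between libraries. The trends were fitted to the same libraries, so the drop cannot tell a technical trend from a response of short transcripts. The prediction set before the test was a median under 0.25 if the trends were the cause and above 0.5 if not; the medians met the second, while the ID8 interval reaches below 0.5. Oxidative phosphorylation (0.33 in PMJ2R, 0.19 to 0.57; 0.46 in ID8) and mitochondrially encoded genes (0.34 in PMJ2R, 0.21 to 0.52; 0.36 in ID8) stayed open. Loss of short-lived messages also stayed open: matched for expression, zinc finger genes differed from other genes by -0.19 in ID8 (-0.31 to -0.04) and -0.30 in PMJ2R, and messages with AU-rich elements by 0.18 in PMJ2R (0.09 to 0.26) and -0.10 in ID8.

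Ahrr, Nqo1 and Cyp1a1 rose in ID8, and activation of the aryl hydrocarbon receptor was weighed against the scaling only. A direct effect of rebastinib on the receptor was not tested. Nqo1 is also on the list of NRF2 antioxidant genes, called higher in ID8 (camera adjusted p = 1.35e-05). NRF2 was not weighed as another source of the rise, for these 3 genes or for the other targets below. A rise of the other targets therefore cannot tell the receptor from NRF2. The other 8 tested targets had a median of 1.48, and 6 of them rose, among them Aldh3a1 (4.51), Gsta1 (4.36) and Tiparp (2.13), which fits the activation, while Cyp1b1 (-0.14, adjusted p = 0.142) and Ugt1a6a (-0.15, adjusted p = 0.548) did not pass the test. Scaled by library totals instead, Cyp1b1 had a ratio of 0.681 (95% counting interval 0.668 to 0.694), Ugt1a6a 0.673 (0.512 to 0.881) and Ugt1a6b, 1 of the 6, 1.06 (0.813 to 1.37), which go against it or leave it open. Nqo1, the lowest of the 3 (3.08, SE 0.0851), lay 1.15 above the highest ribosomal protein gene, Rpl38 (1.93, SE 0.132), and by library totals the ratios stayed at 6.24 for Nqo1, 11.6 for Ahrr and 814 for Cyp1a1 (146 to 32200), which argues against the scaling as the whole cause, although the 3 genes were picked for their rise. Of 5 targets tested in PMJ2R, Tiparp (1.13) and Ugt1a7c (1.50) rose, Ugt1a6a fell (-0.73), Nqo1 did not pass the test (0.28, adjusted p = 0.452), and Ahrr had 76 counts in control and 1 with rebastinib (ratio 0.017, 0.000424 to 0.0975).

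Immediate-early, ERK feedback and cholesterol genes responded differently in the lines by camera at the preset correlation. With an estimated correlation only the cholesterol list among them was called. With length and GC trends removed the smallest share of the median difference that stayed was 1.02 (1.38, 1.62 and 1.09 for the lists, camera adjusted p = 1.57e-13, 3.53e-09 and 1.06e-17), which argues against those trends. The cell line is the biological explanation the design offers, and it cannot be told apart from the different harvest of the lines, with trypsin for ID8 only.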

How the results depend on the processing

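Length and GC correction, removal of genes that overlap ribosomal RNA and the 2-fold minimum were chosen only after the results were seen; the other alternatives were set before the data were examined. Most results kept their direction and their side of the threshold. For named genes, all values were the same in the difference of response (200) and control cells (388), as were 1117 in ID8 and 1194 in PMJ2R, with 3 lost in PMJ2R. Abl1 in ID8 reversed to 0.04 with length and GC trends removed, and the ribosomal protein list of the difference reversed its median (adjusted p = 0.655); the cause was not tested. For lists, 468 values were the same in ID8, 34 gained a call and 18 lost it; in PMJ2R these were 431, 21 and 26, and in the difference 118, 13 and 16. Camera with an estimated correlation called 0 lists in ID8, 0 in PMJ2R and 3 in the difference, and fry, which tests each list by itself, called 30, 30 and 26, where camera at the preset correlation called 11, 13 and 14. With no expression filter 18 lists were called in ID8. With at least a 2-fold difference, 2309 genes were higher and 3622 lower in ID8, and 2187 and 3606 in PMJ2R. With library totals only, 3540 genes were higher in ID8 (5687 with TMM) and 3104 in PMJ2R (5623). Among genes with a mean of at least 5 CPM, where fewer genes are tested, 1578 were higher and 2395 lower between control cells. The correlation between the lines was 0.708 with limma-voom and 0.738 at 5 CPM. It was 0.414 with DESeq2, whose fit took every gene with a count, so that value covers more genes of low expression. The tool and the set of genes were not tested apart. Leaving out each library gave 5462 to 5832 higher and 6004 to 6401 lower genes and 10 to 12 lists in ID8, 5529 to 5753, 5991 to 6219 and 11 to 13 in PMJ2R, and 3301 to 3800 and 4779 to 5150 in the difference. With the replicate number as a block, 5428 genes were higher and 5990 lower in ID8, 5630 and 6096 in PMJ2R, 3386 and 4730 in the difference, and 2882 and 4076 between control cells, and 11 lists were called in each rebastinib comparison and in the difference. The numbers share no known origin, and not every sample correlates best with its own number (ID8 -0.238, -0.0368 and -0.573; PMJ2R 0.12, -0.0207 and 0.0585, where numbers 1 and 3 do; controls of both lines -0.201, 0.0559 and -0.127, where number 2 does). Under the block the calls lost were, in PMJ2R, interferon-stimulated genes (adjusted p = 0.0626) and p53 targets (0.0525), and in the difference alternative macrophage markers (0.0531), angiogenic factors (0.1) and SRF targets (0.0531). Tek, Tie1 and Kdr had 0 counts in both ID8 groups and 1 to 8 counts per group in PMJ2R, too few to compare.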

Other observations

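The genes in this part were chosen after their values were seen. The list of inflammatory cytokines and NF-kB targets was not called in ID8 (4 higher and 10 lower of 21, camera adjusted p = 0.137, called lower at 5 CPM with 0.0435 and with no filter with 0.043, range 0.043 to 0.151 at the preset correlation) or PMJ2R (7 higher and 8 lower of 18, adjusted p = 0.885). Single genes of NF-kB signalling moved: Birc3 fell by 3.01 in ID8 and 3.28 in PMJ2R, Relb (-1.76 and -2.17) and Nfkb2 (-1.28 and -1.40) fell, while the monocyte chemokine gene Ccl7 rose by 2.88 and 2.09. Ptgs2, which encodes cyclooxygenase 2, fell by 1.95 in ID8 and rose by 3.81 in PMJ2R, and Vegfa fell by 0.43 in ID8 and rose by 2.50 in PMJ2R. Xbp1 fell in both (-3.01 and -3.15). The list of apoptosis regulators was not called either (adjusted p = 0.460 and 0.289), and of its members Bmf (-2.86 and -6.97) and Bcl2 (-1.65 and -1.82) fell and Bbc3 (1.15 and 1.87) and Bcl2l1 (1.13 and 1.34) rose. The metal-binding genes Mt1 (3.66 and 1.02) and Mt2 (8.33 and 2.88) rose, Mt2 sharing exons with Gm45774.

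Replication-dependent histone genes were mostly higher, with 14 of 18 tested higher and 1 lower in ID8 (median 1.37, camera adjusted p = 0.105) and 12 of 13 higher and 1 lower in PMJ2R (median 1.87, adjusted p = 0.101), and the list was called with library totals only (0.0122 and 0.00935) and with no filter (0.0324 and 0.00108; range over alternatives 0.0122 to 0.559 and 0.00108 to 0.219 at the preset correlation). Processed pseudogenes had a median of 1.33 in ID8 (535 genes) and 0.76 in PMJ2R (634), small nucleolar RNA genes 1.88 (69) and 1.16 (56), and long intergenic RNA genes -0.71 (300) and -0.46 (313). The same rebastinib libraries held more counts in genes that overlap ribosomal RNA (1.23% against 0.211% in ID8, 5.82% against 0.128% in PMJ2R). For histone and small nucleolar RNA genes, a change in what the preparation captured therefore cannot be told apart from a change in expression. Of 26 macrophage markers, 17 stood at 10 or more CPM in PMJ2R control and 1 in ID8 control; of 26 ovarian markers, 0 did in PMJ2R control and 16 in ID8 control.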
